A study of Mus musculus with 8 samples.

How the data were processed

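Gene expression was measured on 8 Affymetrix mouse whole-genome arrays, which carry several short-oligonucleotide probe sets for many genes. The labels put the arrays into 4 groups of 2: C2C12 myotubes infected with adenovirus for GFP or for GFP-tagged PGC-1α, each with or without 100 µM deferoxamine (DFO). The series' design text calls the arrays of a group biological duplicates. RNA was purified on spin columns and labelled as biotinylated cRNA, per the labels' protocols.

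The deposited values are probe-set intensities on a linear scale, 1 table per array. How the authors summarised probes into probe sets, corrected background and scaled the arrays is not given in the sources used here. Array medians of 59.3 to 62.6 show that the deposited intensities had been brought to about the same level, and 968 to 1082 values per array were exactly 1. A true difference in total RNA between groups cannot be seen on values of that kind. Values were used as deposited and log2-transformed, with no pseudocount and no filter on dim genes. Gene symbols came from the platform annotation: of 45101 probe sets, 34945 had 1 symbol, 932 had several, 9160 had none and 64 were control probe sets. Each of the 18193 genes was represented by the probe set with the highest mean over the 8 arrays among those with that symbol alone, and 9010 genes had over 1 probe set. No genome build was given, so no coordinates are reported.

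limma 3.58.1 in R 4.3.3 fitted 1 mean per group to all 8 arrays (4 residual and 1.3 prior degrees of freedom), with eBayes without trend or robust options. There were 6 contrasts: the construct without and with DFO, DFO with GFP and with PGC-1α, their interaction, and both together against GFP. Adjusted p-values are two-sided Benjamini-Hochberg values over all genes of a contrast, called at 0.05. Log2 changes are given ± the SE from limma, intensities as mean ± SD of 2 arrays. The smallest two-sided p of an exact permutation test of 2 arrays against 2 is 0.333, so p-values here rest on limma's pooled spread. The number of arrays limits their precision, as does signal over background for dim genes.

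Of 35 gene lists 34 had 2 or more measured members and were tested with camera, limma's test of whether a list moved relative to all other genes, at a preset correlation of 0.01. Over the 204 tests, 109 passed an adjusted p of 0.05. With the correlation estimated from the residuals, camera passed 0 of them, the count at an unadjusted p under 0.05 was 53, and fry, which tests whether a list's genes moved on balance one way without comparing them with other genes, passed 152. Each list call is printed with its p under the estimated correlation. Lists share members, mostly among the respiratory complexes and the iron-sulfur and haem enzymes. The list of mitochondrially encoded transcripts had 1 measured gene and was not tested.

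The named genes followed a rule. For each of the 4 single-factor contrasts it took the 6 largest rises and 6 largest falls past the threshold among genes above the median level whose groups did not overlap, and up to 3 members of each called list with the largest change in the list's direction. For the interaction it took 6 on each side, with no rule on overlap. Predicted transcripts were passed over. It always took Ppargc1a, Esrra, Cycs, Sdhb, Ndufs1, Cs, Pdk4, Tfrc, Fth1, Slc40a1, Vegfa, Egln3, Ldha, Myog and Cdkn1a, which were the genes named for both factors together. The groups, contrasts, tests, lists, this rule and the alternatives were chosen before the data were examined, except where stated. The alternatives were quantile normalization, median centring, the mean of a gene's probe sets, no probe sets ending in _x_at or _s_at, every probe set on its own, genes above the median level, a floor at the 25th percentile of each array, eBayes with trend and robust options, a fit of only the groups compared, a change of at least 2-fold, the replicate number as a block, fry, the estimated correlation, and each array left out. Scaling to the 24 poly-A spike-in probe sets, and splitting the 2 GFP arrays between the construct and DFO, were chosen after seeing the data.

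The procedure was tested on simulated data made from the contrast of PGC-1α with GFP without DFO, over 18193 genes. It recovered 0 of 67 genes with a true log2 change of 0.5, 14 of 67 (20.9%) at 1 and 39 of 66 (59.1%) at 2, the last being 30 of 33 among genes above the median level, and it called 4 of 17963 unchanged genes. The simulation changed 200 genes and a list of 30, while limma passed 1770 genes in the data. With so few changed genes the adjusted threshold was stricter, so these rates do not give the recovery in the data. A gene that did not pass may still have changed. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.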

Results

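RNA was measured in C2C12 myotubes, the multinucleated muscle cells that this established mouse myoblast line forms when serum is lowered. After 3 days in 2% serum the cells received adenovirus for GFP alone or for GFP-tagged PGC-1α, a transcriptional coactivator of genes of mitochondrial energy metabolism, and RNA was taken 3 days later. Some cultures also received 100 µM deferoxamine (DFO), which binds ferric iron. The 4 groups, GFP, PGC-1α, GFP plus DFO and PGC-1α plus DFO, held 2 arrays each. Array medians lay between 59.3 and 62.6 intensity units. Log2 intensities of the 2 arrays of a group correlated with r from 0.942 to 0.962 across probe sets, which are not independent replicates. The median SD of log2 intensity within a group was 0.0556 to 0.112 among genes above the median level and 0.212 to 0.306 among dimmer genes. The ratio of 5' to 3' signal of beta-actin, a sign of RNA integrity, was 0.753 and 0.811 on the 2 arrays of PGC-1α plus DFO 0.868 and 0.859 on those of GFP plus DFO and 0.897 to 0.921 on the 4 without DFO. That of Gapdh was 1.12 on both arrays of GFP plus DFO against 1.17 and 1.2 with GFP, so changes with DFO were measured on RNA with somewhat lower ratios in both pairs of groups.

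The probe set used for Ppargc1a, the gene of PGC-1α, read 33.0 ± 6.11 intensity units with GFP and 7124 ± 123 with the construct (SD, n = 2), a log2 change of 7.77 ± 0.55 (SE; limma adjusted p = 0.00315). With DFO it read 57.4 ± 43.5 and 7820 ± 156 (log2 change 7.33 ± 0.55, adjusted p = 0.00174). The other 4 probe sets of Ppargc1a did not rise with the construct. In a fit of every probe set 1 of them fell by 1.60 ± 0.18 (adjusted p = 0.0217), and the other 3 had log2 changes of -0.81, -0.28 and -0.81 (adjusted p = 0.167, 0.643 and 0.141). With DFO in GFP cells 3 of the 4 fell, with log2 changes of -1.39, -0.97 and -1.45 (adjusted p = 0.0231, 0.0279 and 0.0158), while the brightest probe set had 0.57 ± 0.55 (adjusted p = 0.531). Which part of the transcript each probe set covers was not analysed here, so construct and cellular transcript were not separated.

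The first comparison set PGC-1α against GFP without DFO. Genes of the TCA cycle and of the respiratory chain rose together. Cs, citrate synthase, went from 3255 ± 6.79 to 7990 ± 76.6 intensity units (SD, n = 2), a log2 change of 1.30 ± 0.08 (SE; limma adjusted p = 0.00256). Idh3a, a subunit of mitochondrial isocitrate dehydrogenase, rose by 1.95 ± 0.09 (adjusted p = 0.00168), and Esrra, the nuclear receptor ERRα that PGC-1α coactivates, by 2.21 ± 0.10 (adjusted p = 0.00168). Cox7a1, the muscle and heart isoform of a cytochrome c oxidase subunit, rose by 3.64 ± 0.09 (adjusted p = 0.000633) and Sdhb of complex II by 1.14 ± 0.09 (adjusted p = 0.00433).

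By list, 27 of 33 measured complex I subunits rose and 1 fell, 13 of 14 genes of complexes II and III with cytochrome c rose, 11 of 13 of complex IV, 10 of 17 of ATP synthase and 14 of 17 of the TCA cycle. Adjusted over the list alone, the rises were 29, 13, 11, 15 and 16. Median log2 changes of the 5 lists were 0.66, 0.86, 0.50, 0.50 and 0.85. Camera gave adjusted p = 1.53e-20, 5.59e-15, 1.55e-08, 5.61e-11 and 1.85e-16, and adjusted p = 0.161, 0.0882, 0.102, 0.141 and 0.0822 with an estimated correlation. Ndufb10 and Ndufb5 of complex I rose by 1.39 ± 0.10 and 0.99 ± 0.08, Uqcrc1 and Uqcrfs1 of complex III by 1.22 ± 0.10 and 1.21 ± 0.08, and Dlat of pyruvate dehydrogenase by 1.56 ± 0.08. The mitochondrial enzymes that carry iron-sulfur clusters or haem, which share members with these lists, rose in 17 of 20 (18 adjusted over the list alone). The median was 0.85, with adjusted p = 1.69e-17 by camera and adjusted p = 0.0822 with an estimated correlation.

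Genes of fatty acid oxidation rose in 14 of 20 members (15, and 2 falls, adjusted over the list alone). The median was 0.92, with adjusted p = 1.13e-12 by camera and adjusted p = 0.0822 with an estimated correlation. Among them were Acadvl, an acyl-CoA dehydrogenase (1.54 ± 0.10), Fabp3, a fatty acid binding protein (1.48 ± 0.09), and Etfdh, which passes electrons to ubiquinone (1.31 ± 0.08). Of 72 genes of the mitochondrial ribosome 39 rose and 0 fell by limma (54 rises adjusted over the list alone), led by Mrpl47 at 2.08 ± 0.13. The median was 0.54, with adjusted p = 1.71e-26 by camera and adjusted p = 0.141 with an estimated correlation. Genes of mitochondrial gene expression and biogenesis rose in 13 of 27 (17 adjusted over the list alone). The median was 0.57, with adjusted p = 9.69e-12 by camera and adjusted p = 0.189 with an estimated correlation. Iron-sulfur cluster assembly rose in 11 of 18 (13, and 1 fall, adjusted over the list alone). The median was 0.68, with adjusted p = 5.8e-09 by camera and adjusted p = 0.141 with an estimated correlation. Its ferredoxin Fdx1 went from 386 ± 24.4 to 3924 ± 41.0 (log2 change 3.35 ± 0.09), and Bola3 rose by 1.24 ± 0.08.

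Of the 24 partners and known targets of PGC-1α, a list drawn up from knowledge of the coactivator, 9 rose and 1 fell (11 and 1 adjusted over the list alone). The median was 0.46, with adjusted p = 4.1e-08 by camera and adjusted p = 0.0822 with an estimated correlation. Ckmt2, mitochondrial creatine kinase, rose by 2.93 ± 0.12, Lpin1 by 2.38 ± 0.15 and Pdk4, which inhibits pyruvate dehydrogenase, by 2.28 ± 0.10. Antioxidant enzymes rose in 5 of 16 and fell in 1, with Sod2 at 1.64 ± 0.08 and Prdx3 at 0.98 ± 0.08 (6 and 2 adjusted over the list alone). The median was 0.25, with adjusted p = 0.0123 by camera and adjusted p = 0.391 with an estimated correlation. This call ended without PGC-1α replicate 2 (adjusted p = 0.0502). Glycolysis rose in 4 of 15 and fell in 1, with Hk1 at 1.47 ± 0.10 and Pgam1 at 1.02 ± 0.09 (6 and 2 adjusted over the list alone). The median was 0.22, with adjusted p = 0.00983 by camera and adjusted p = 0.337 with an estimated correlation. Branched chain amino acid breakdown rose in 4 of 17, with Hibadh at 1.05 ± 0.09 (5 adjusted over the list alone). The median was 0.31, with adjusted p = 0.000171 by camera and adjusted p = 0.278 with an estimated correlation. Angiogenic factors rose in 2 of 11, Vegfb by 1.40 ± 0.17 and Vegfa by 0.73 ± 0.09, gene calls that each ended without any of 3 arrays (2 adjusted over the list alone), and the calls of Vegfa (adjusted p = 0.0567) and of the list (adjusted p = 0.053) ended when arrays were scaled to their poly-A spike-ins. The median was 0.34, with adjusted p = 0.019 by camera and adjusted p = 0.213 with an estimated correlation. With that scaling the median was 0.51 and Vegfa rose by 0.91, so neither rise was smaller where its call ended.

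In the muscle differentiation list 6 of 20 fell and 0 rose by limma (7 falls adjusted over the list alone). Fast sarcomere genes fell in 2 of 13 and rose in 1 (6 and 1 adjusted over the list alone). The medians were -0.38 and -0.34, and -0.20 and -0.17 on the spike-in scale. Camera gave adjusted p = 0.00125 and 0.00956, and adjusted p = 0.48 and 0.375 with an estimated correlation. The call of the fast list ended on the spike-in scale (adjusted p = 0.06). So did those for falls of Myh3, Myh8, Chrng and Atp2a1 (limma adjusted p = 0.087, 0.259, 0.185 and 0.578). Mybpc2, a myosin-binding protein, had -1.60 ± 0.14. Myog, a transcription factor of muscle differentiation, had a log2 change of -0.00 ± 0.13 (adjusted p = 0.997). Leading rises besides Ppargc1a were Upp1, uridine phosphorylase (4.17 ± 0.08), Nppb, a natriuretic peptide (4.03 ± 0.15), Spsb4 (3.76 ± 0.22), Gmnn, geminin (3.55 ± 0.38), and Cox7a1. Leading falls were Setd5 (-2.83 ± 0.11), the heat shock genes Hspa1a (-2.54 ± 0.32) and Hspa1b (-1.91 ± 0.09), Nmd3 (-2.44 ± 0.33), Ager (-2.01 ± 0.13) and Reep1 (-1.96 ± 0.17). The Gmnn call ended without PGC-1α replicate 1 (adjusted p = 0.0633) or 2 (0.0546). That of Nmd3 ended without GFP replicate 1 (adjusted p = 0.0858) or 2 (0.0688) or either array of GFP plus DFO (0.0527), and it did not pass with the mean of its probe sets. Without probe sets ending in _x_at or _s_at, Reep1 rose by 0.78 and Ager had 0.13, so the direction of both depended on the probe set.

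Among iron genes Tfrc, the transferrin receptor, rose from 4124 ± 296 to 7847 ± 217 (log2 change 0.93 ± 0.09, adjusted p = 0.00676). Fth1, ferritin heavy chain, had -0.12 ± 0.09 (adjusted p = 0.431) and Slc40a1, the iron exporter ferroportin, -0.45 ± 0.11 (adjusted p = 0.0626). Egln3, an oxygen sensor that marks hypoxia-inducible factor for breakdown, fell by 0.99 ± 0.09 (adjusted p = 0.00503, and 0.0575 on the spike-in scale). The list of hypoxia-inducible factor targets, with 5 rises and 3 falls among 25, did not pass (7 and 5 adjusted over the list alone; adjusted p = 0.103). In all, limma passed 1770 of 18193 genes, 902 higher and 868 lower, with 5036 at an unadjusted p under 0.05. The count was 455 without GFP replicate 1, 709 without GFP replicate 2, 304 without PGC-1α replicate 1, 508 without PGC-1α replicate 2 and 638 without either array of GFP plus DFO, with between 10 and 22 of 64 named calls ended. Tfrc ended without PGC-1α replicate 1 (adjusted p = 0.0544) or 2 (0.0503). Hspa1a ended without GFP replicate 1 (0.072) or 2 (0.0663) or PGC-1α replicate 1 (0.0553), Vegfb without GFP replicate 1 (0.072) or 2 (0.0617) or PGC-1α replicate 2 (0.0527), and Vegfa without GFP replicate 1 (0.0665) or PGC-1α replicate 1 (0.084) or 2 (0.0674). A fit of only these 4 arrays passed 0 genes (4531 at an unadjusted p under 0.05), and scaling to the spike-ins, which moved the median change of all genes from -0.08 to 0.09 and each list by as much, passed 508, 86.2% of them higher against 51% on the deposited scale.

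**Figure D1:**
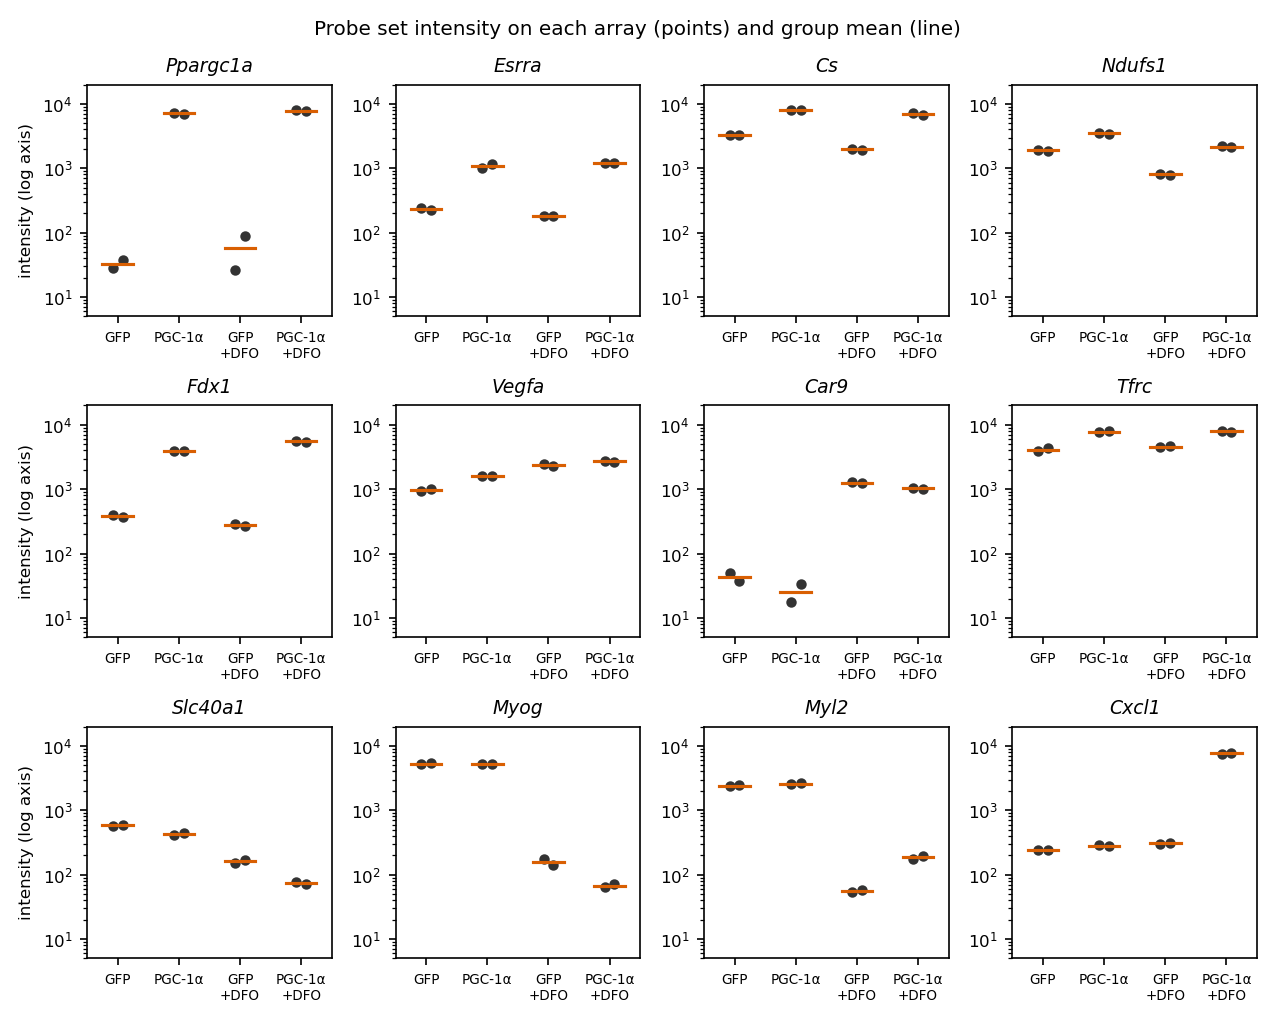
Intensity of 12 genes on the 8 arrays, on a log axis in linear intensity units, with a point for each array and a line at the mean of each group. Fdx1 sat near 386 with GFP and 3924 with PGC-1α, while Myog sat near 5277 with GFP and 157 with GFP plus DFO.

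The second comparison set DFO against no DFO in GFP cells. Targets of hypoxia-inducible factor, a transcription factor that iron-dependent hydroxylases mark for breakdown, rose, and genes of muscle differentiation and mitochondrial metabolism fell. Car9, a carbonic anhydrase, went from 43.1 ± 8.61 to 1264 ± 34.4 intensity units (SD, n = 2), a log2 change of 4.89 ± 0.31 (SE; limma adjusted p = 0.000629), and Vegfa rose by 1.27 ± 0.09 (adjusted p = 0.000816). Myog fell from 5277 ± 75.5 to 157 ± 23.4, a log2 change of -5.08 ± 0.13 (adjusted p = 0.000139). Ndufs1, an iron-sulfur subunit of complex I, fell from 1888 ± 52.1 to 803 ± 26.2 (log2 change -1.23 ± 0.08, adjusted p = 0.000631).

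Of 25 measured targets of hypoxia-inducible factor 23 rose and 0 fell by limma (23 adjusted over the list alone), with Ankrd37 at 4.61 ± 0.12 and Egln3 at 1.32 ± 0.09. The median was 2.28, with adjusted p = 1.3e-21 by camera and adjusted p = 0.0822 with an estimated correlation. Glycolysis rose in 11 of 15 and fell in 3 (11 and 3 adjusted over the list alone). The median was 1.18, with adjusted p = 0.000401 by camera and adjusted p = 0.251 with an estimated correlation. Aldoc, an aldolase, rose by 3.76 ± 0.22 and Pfkl, liver phosphofructokinase, by 2.14 ± 0.12. The 3 that fell are muscle isoforms: Pgam2 at -4.34 ± 0.21 and, named after their values were seen, Eno3 at -2.68 ± 0.09 and Pfkm at -1.75 ± 0.08. Angiogenic factors rose in 5 of 11 and fell in 1, with Pgf, placental growth factor, at 5.01 ± 0.24 and Apln, apelin, at 4.83 ± 0.17 (6 and 1 adjusted over the list alone). The median was 1.07, with adjusted p = 0.00838 by camera and adjusted p = 0.183 with an estimated correlation. Cholesterol synthesis rose in 13 of 14, with Stard4 at 2.85 ± 0.10, Msmo1 at 2.27 ± 0.09 and Hmgcs1 at 2.13 ± 0.10 (13 adjusted over the list alone). The median was 1.74, with adjusted p = 2.77e-11 by camera and adjusted p = 0.118 with an estimated correlation.

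Muscle differentiation genes fell in 17 of 20 (19 adjusted over the list alone), with Ckm, muscle creatine kinase, at -3.28 ± 0.09 and Actn2, an actinin of the Z-disc, at -3.10 ± 0.12. The median was -1.95, with adjusted p = 1.62e-13 by camera and adjusted p = 0.189 with an estimated correlation. Fast sarcomere genes fell in 11 of 13 (12 adjusted over the list alone) and slow and cardiac sarcomere genes in 12 of 14 (12 adjusted over the list alone). The medians were -1.70 and -1.47, with adjusted p = 2.11e-09 and 8.08e-10 by camera and adjusted p = 0.141 and 0.118 with an estimated correlation. Examples were the calcium pump Atp2a1 at -3.07 ± 0.08, the myosin heavy chain Myh4 at -2.98 ± 0.13, the myosin light chain Myl2 at -5.43 ± 0.10 and myoglobin, Mb, at -2.17 ± 0.09. Markers of undifferentiated myoblasts and reserve cells, some of which myotubes may also express, rose in 4 of 16 and fell in 6, and the list did not pass (4 and 6 adjusted over the list alone; median -0.24; adjusted p = 0.537).

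Among mitochondrial lists, 29 of 33 complex I subunits fell and 1 rose. Falls were 11 of 14 genes of complexes II and III, 6 of 13 of complex IV, 14 of 17 of ATP synthase and 15 of 17 of the TCA cycle, with 0 rises by limma. Adjusted over the list alone, the falls were 29, 12, 8, 16 and 15. Medians were -0.70, -0.50, -0.27, -0.39 and -0.81, with adjusted p = 3.77e-13, 2.08e-06, 0.000879, 3.66e-07 and 1.56e-08, and adjusted p = 0.218, 0.178, 0.192, 0.183 and 0.118 with an estimated correlation. Iron-sulfur and haem enzymes of mitochondria fell in 17 of 20 (17 adjusted over the list alone), with Ndufs8 at -1.46 ± 0.11 and Ndufv1 at -1.02 ± 0.09. The median was -0.64, with adjusted p = 1.91e-09 by camera and adjusted p = 0.0882 with an estimated correlation. Other falls were Fh1, fumarase, at -1.15 ± 0.09, Cyc1 of complex III at -0.97 ± 0.07 and Cox6a2, a muscle isoform of complex IV, at -2.70 ± 0.08. Fatty acid oxidation fell in 16 of 20 and rose in 1 (17 and 1 adjusted over the list alone), with the fatty acid transporter Cd36 at -3.38 ± 0.30. The median was -0.77, with adjusted p = 1.12e-08 by camera and adjusted p = 0.0882 with an estimated correlation. The mitochondrial ribosome fell in 47 of 72 and rose in 1 (49 and 2 adjusted over the list alone), and mitochondrial gene expression and biogenesis fell in 11 of 27, with Tfam, which binds mitochondrial DNA, at -0.77 ± 0.08 (14, and 3 rises, adjusted over the list alone). The medians were -0.56 and -0.27, with adjusted p = 4.24e-13 and 0.00323 by camera and adjusted p = 0.244 and 0.48 with an estimated correlation.

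Breakdown of branched chain amino acids fell in 13 of 17, with Pccb at -2.20 ± 0.10 and Ivd at -1.73 ± 0.09 (13 adjusted over the list alone). The median was -0.88, with adjusted p = 1.57e-06 by camera and adjusted p = 0.204 with an estimated correlation. The list of ATF4 and the integrated stress response fell in 13 of 22 and rose in 4, with the hormone Fgf21 at -5.02 ± 0.23 and Phgdh, of serine synthesis, at -2.36 ± 0.09 (14 and 4 adjusted over the list alone). The median was -0.62, with adjusted p = 0.00467 by camera and adjusted p = 0.313 with an estimated correlation. Collagens and matrix genes rose in 9 of 22 and fell in 4, with the lysyl oxidase Lox at 2.96 ± 0.09 and Col5a2 at 1.55 ± 0.09 (12 and 5 adjusted over the list alone). The median was 0.38, with adjusted p = 0.0139 by camera and adjusted p = 0.533 with an estimated correlation. Beside these, the monocyte markers Cd14 and Cd68, named here after their values were seen, rose by 2.50 ± 0.11 and 1.34 ± 0.16, the 2 of 13 macrophage, endothelial and red cell markers that passed (2 adjusted over the list alone; adjusted p = 0.19 for the list).

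The iron exporter Slc40a1 fell from 581 ± 17.6 to 160 ± 13.6 (log2 change -1.86 ± 0.11, adjusted p = 0.000479). Tfrc had 0.16 ± 0.09 (adjusted p = 0.287), Fth1 -0.29 ± 0.09 (adjusted p = 0.0687) and Cdkn1a, a cell cycle inhibitor, -0.20 ± 0.08 (adjusted p = 0.129). Other leading changes were rises of Vwa1 (5.04 ± 0.12), Fosl1, an AP-1 subunit (5.03 ± 0.26), and Sprr2h (4.91 ± 0.38) and falls of Tceal7 (-4.93 ± 0.11) and C1qtnf3 (-4.31 ± 0.25). Limma passed 4409 genes, 2140 higher and 2269 lower, with 6502 at an unadjusted p under 0.05. The count was 2674 without GFP replicate 1, 2135 without GFP plus DFO replicate 1 and 2069 without GFP plus DFO replicate 2. It was 2230 with arrays scaled to the spike-ins, which differed between these 2 groups by a log2 change of 0.00 ± 0.12 (adjusted p = 0.998), so that scaling could not turn the direction of lists here.

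**Figure D2:**
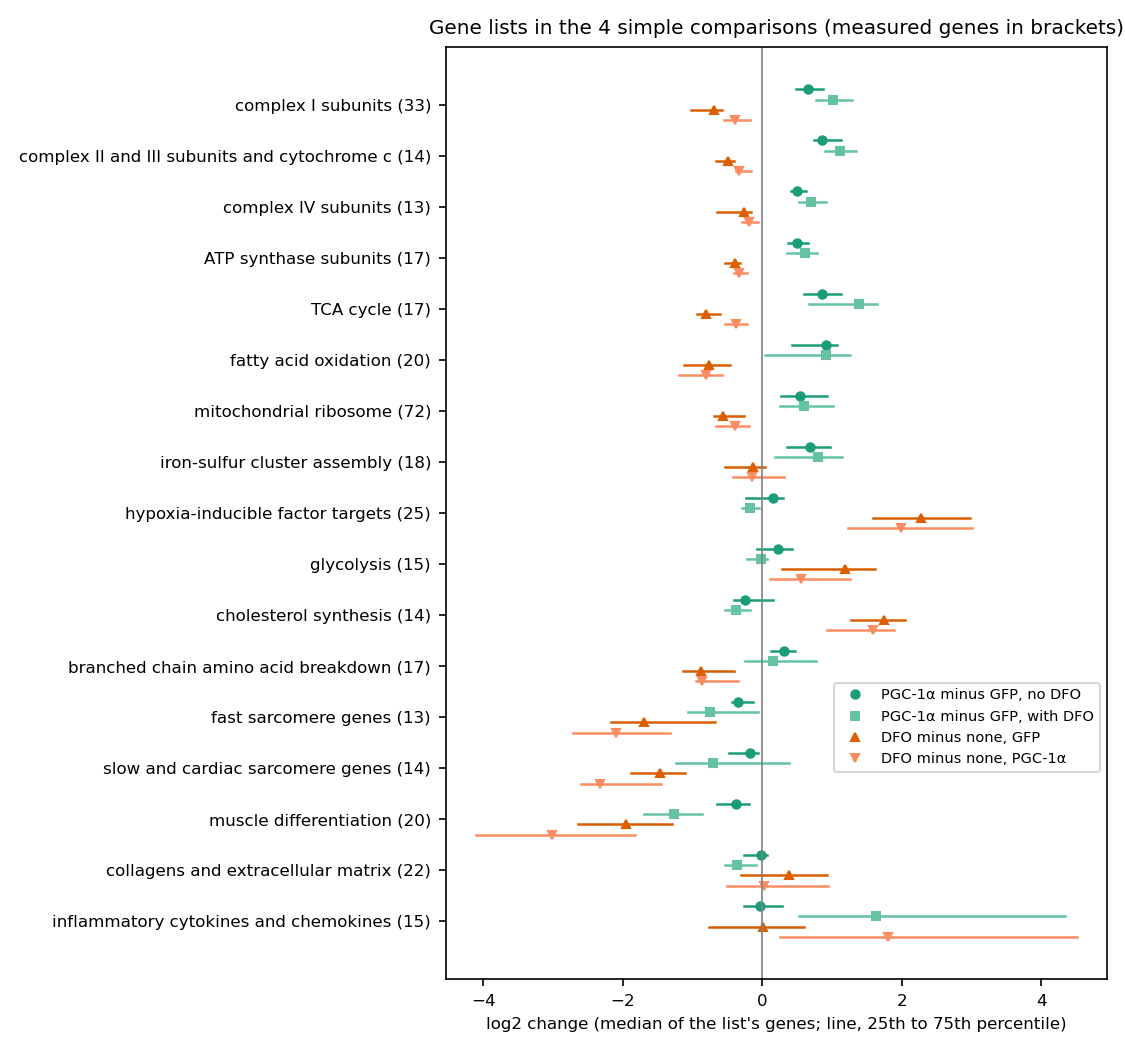
Median log2 change of 17 gene lists in the 4 single-factor comparisons, with bars from the lower to the upper quartile of the members. In GFP cells the hypoxia-inducible factor targets sat at 2.28 with DFO and complex I at -0.70, and complex I sat at 0.66 with PGC-1α alone; with PGC-1α present complex I sat at -0.39 with DFO, a direction that turned to 0.05 with arrays scaled to the spike-ins.

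The third comparison set PGC-1α against GFP with DFO present in both. Mitochondrial genes rose with the construct in DFO-treated cells, a set of chemokines rose, and muscle genes fell. Cs went from 1956 ± 21.8 to 6975 ± 226 intensity units (SD, n = 2), a log2 change of 1.83 ± 0.08 (SE; limma adjusted p = 0.000756), and Fdx1 from 278 ± 7.69 to 5528 ± 141 (4.31 ± 0.09, adjusted p = 0.000196). Cxcl1, a chemokine that attracts neutrophils, went from 304 ± 9.45 to 7654 ± 146 (4.65 ± 0.08, adjusted p = 0.000196). Chrng, an acetylcholine receptor subunit of immature muscle, fell from 709 ± 2.55 to 118 ± 9.12 (-2.58 ± 0.09, adjusted p = 0.000524). The poly-A spike-in RNAs read lower on the arrays of PGC-1α plus DFO, by a log2 change of -0.62 ± 0.12 against GFP (adjusted p = 0.0173), and scaling to them moved the median change of all genes in this comparison from -0.05 to 0.57 and each list by as much, so changes here are relative to the deposited scale.

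Complex I subunits rose in 28 of 33, complexes II and III with cytochrome c in 14 of 14, complex IV in 11 of 13, ATP synthase in 12 of 17 and the TCA cycle in 15 of 17, with 0 falls by limma in the 5 lists. Adjusted over the list alone, the rises were 29, 14, 12, 14 and 15. Medians were 1.01, 1.12, 0.70, 0.61 and 1.38, with adjusted p = 3.01e-24, 9.5e-15, 9.37e-11, 3.06e-09 and 1.22e-14, and adjusted p = 0.141, 0.0882, 0.0882, 0.149 and 0.0882 with an estimated correlation. Examples were Ndufs8 at 1.65 ± 0.11, Ndufs1 at 1.43 ± 0.08, Cyc1 at 1.57 ± 0.07, Cycs, cytochrome c, at 1.29 ± 0.12 and Idh3a at 2.56 ± 0.09. Iron-sulfur and haem enzymes rose in 17 of 20 and fell in 1 (18 and 1 adjusted over the list alone), and iron-sulfur cluster assembly rose in 11 of 18 (13 adjusted over the list alone). The medians were 1.27 and 0.80, with adjusted p = 4.04e-16 and 1.92e-08 by camera and adjusted p = 0.0822 and 0.141 with an estimated correlation. Fatty acid oxidation rose in 13 of 20 and fell in 1, with Hadha at 1.77 ± 0.10 (13 and 2 adjusted over the list alone). The median was 0.91, with adjusted p = 3.75e-07 by camera and adjusted p = 0.0882 with an estimated correlation. The mitochondrial ribosome rose in 45 of 72 (53, and 3 falls, adjusted over the list alone), and mitochondrial gene expression and biogenesis in 17 of 27 with 1 fall (17 and 3 adjusted over the list alone). The medians were 0.60 and 0.65, with adjusted p = 2.53e-21 and 3.87e-08 by camera and adjusted p = 0.166 and 0.258 with an estimated correlation. Partners and targets of PGC-1α rose in 7 of 24 and fell in 1, with Esrra at 2.72 ± 0.10 and Sod2 at 2.52 ± 0.08 (8 and 3 adjusted over the list alone). The median was 0.39, with adjusted p = 0.000474 by camera and adjusted p = 0.118 with an estimated correlation.

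Inflammatory cytokines and chemokines rose in 10 of 15 and 0 fell by limma (11 rises adjusted over the list alone). The median was 1.63, with adjusted p = 9.13e-09 by camera and adjusted p = 0.0822 with an estimated correlation. Cxcl5 went from 31.5 ± 15.0 to 900.0 ± 65.6 and the acute phase gene Saa3 from 9.21 ± 3.22 to 396 ± 36.2. Il6, interleukin 6, named for DFO in PGC-1α cells by the rule, went from 29.3 ± 3.99 to 581 ± 48.4 here. Macrophage, endothelial and red cell markers passed in 0 of 13 by limma (0 adjusted over the list alone; list adjusted p = 0.322), with Cd14 at 485 ± 22.0 and 447 ± 27.4 and Cd68 at 84.0 ± 3.56 and 80.2 ± 8.85. The beta-actin ratio of 5' to 3' signal was 0.859 and 0.868 with GFP plus DFO against 0.753 and 0.811 with PGC-1α plus DFO.

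Muscle differentiation genes fell in 16 of 20 and rose in 1 (17 and 1 adjusted over the list alone), with Tmem182 at -3.06 ± 0.16 and Cav3, caveolin 3, at -3.03 ± 0.34. The median was -1.27, with adjusted p = 1.55e-08 by camera and adjusted p = 0.272 with an estimated correlation. Myog fell by 1.22 ± 0.13 (adjusted p = 0.00438), a call that ended on the spike-in scale (adjusted p = 0.0582). Fast sarcomere genes fell in 9 of 13, with Tnni2, a fast troponin, at -1.45 ± 0.10 (9, and 1 rise, adjusted over the list alone). The median was -0.76, with adjusted p = 0.000171 by camera and adjusted p = 0.258 with an estimated correlation. Slow and cardiac sarcomere genes fell in 9 of 14 and rose in 2, with Casq2, cardiac calsequestrin, at -1.64 ± 0.09 (9 and 4 adjusted over the list alone), a call that ended without PGC-1α plus DFO replicate 1 (adjusted p = 0.0689). The median was -0.71, with adjusted p = 0.0242 by camera and adjusted p = 0.375 with an estimated correlation. On the spike-in scale the medians of the 3 lists were smaller, at -0.65 for muscle differentiation, -0.14 for fast and -0.0942 for slow and cardiac sarcomere genes. The leading falls were Pdlim3 (-4.04 ± 0.08), Ldb3 (-3.80 ± 0.41), Tgfb3 (-3.07 ± 0.09), Tmem182, the myosin chaperone Unc45b (-2.95 ± 0.23) and the ubiquitin ligase Trim63 (-2.92 ± 0.19). The leading rises besides Ppargc1a, Cxcl1 and Fdx1 were Nppb (5.34 ± 0.15), the neurofilament gene Nefm (4.37 ± 0.12) and Mcrip2 (3.82 ± 0.10).

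Several lists moved down on the deposited scale and up on the spike-in scale, where the call of each ended. Collagens and matrix genes fell in 11 of 22 (12 adjusted over the list alone), with Postn, periostin, at -1.49 ± 0.09 and Ccn2 at -1.25 ± 0.09, which had -0.63 with adjusted p = 0.0573 on the spike-in scale (median -0.36, and 0.25 on the spike-in scale; adjusted p = 0.000651, adjusted p = 0.426 with an estimated correlation). Cholesterol synthesis fell in 4 of 14 (7 adjusted over the list alone). The median was -0.38, and 0.24 on the spike-in scale, with adjusted p = 0.00285 by camera and adjusted p = 0.313 with an estimated correlation. Targets of p53 fell in 6 of 16, with Pmaip1 at -1.05 ± 0.10, which had -0.43 with adjusted p = 0.0876 on the spike-in scale (6, and 1 rise, adjusted over the list alone). The median was -0.29, and 0.33 on the spike-in scale, with adjusted p = 0.0184 by camera and adjusted p = 0.356 with an estimated correlation. Lysosome and autophagy genes fell in 4 of 19 and rose in 1 (5 and 1 adjusted over the list alone), and that call ended without either PGC-1α array (adjusted p = 0.0587), PGC-1α plus DFO replicate 2 (adjusted p = 0.213) or GFP plus DFO replicate 1 (adjusted p = 0.0556) or 2 (adjusted p = 0.0898). The median was -0.23, and 0.38 on the spike-in scale, with adjusted p = 0.0443 by camera and adjusted p = 0.656 with an estimated correlation. Muscle atrophy ligases fell in 2 of 7 (3 adjusted over the list alone), a call that ended without either PGC-1α array (adjusted p = 0.0573), PGC-1α plus DFO replicate 2 (adjusted p = 0.0656) or GFP plus DFO replicate 1 (adjusted p = 0.0979). The median was -0.27, and 0.34 on the spike-in scale, with adjusted p = 0.0445 by camera and adjusted p = 0.323 with an estimated correlation.

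Tfrc rose by 0.78 ± 0.09 (adjusted p = 0.00566) and Slc40a1 fell by 1.11 ± 0.11 (adjusted p = 0.0034), the first ending without GFP plus DFO replicate 1 (adjusted p = 0.0561) and the second on the spike-in scale (adjusted p = 0.124). Egln3 fell by 1.22 ± 0.09 (adjusted p = 0.00156), and Vegfa had 0.22 ± 0.09 (adjusted p = 0.169). Limma passed 3446 genes, 1260 higher and 2186 lower, with 5864 at an unadjusted p under 0.05. The count was 2135 without PGC-1α plus DFO replicate 2, 873 without GFP plus DFO replicate 1 and 1070 without GFP plus DFO replicate 2, and 861 in a fit of only these 4 arrays. The share of calls that were higher was 36.6% on the deposited scale and 94% on the spike-in scale.

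**Figure D3:**
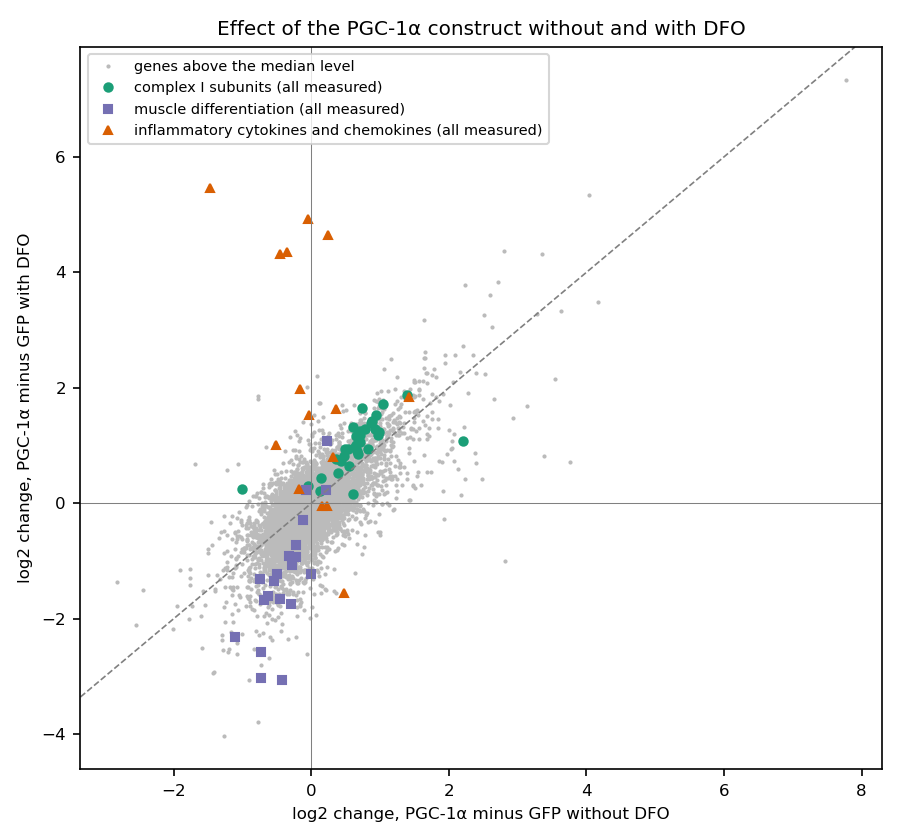
Log2 change with the construct without DFO (horizontal axis) and with DFO (vertical axis) for genes above the median level, 1 point per gene, with complex I, muscle differentiation and inflammatory genes coloured and a dashed line of equal change. Across these genes, which are not independent replicates, r was 0.715, and the median of the muscle differentiation genes was -0.38 without and -1.27 with DFO.

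The fourth comparison set DFO against no DFO in PGC-1α cells. Hypoxia-inducible factor targets rose and muscle genes fell here too. Car9 went from 25.7 ± 10.8 to 1031 ± 37.1 intensity units (SD, n = 2), a log2 change of 5.39 ± 0.31 (SE; limma adjusted p = 0.000406), and Myog from 5270 ± 36.5 to 67.1 ± 5.64 (-6.30 ± 0.13, adjusted p = 6.42e-05). Il6 went from 15.7 ± 11.3 to 581 ± 48.4 (5.43 ± 0.51, adjusted p = 0.00172). The poly-A spike-ins and the beta-actin ratio were lower on the DFO arrays of this comparison, as given above, and scaling to the spike-ins moved the median change of all genes from 0.01 to 0.45 and each list by as much.

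Targets of hypoxia-inducible factor rose in 23 of 25 (24 adjusted over the list alone). The median was 1.99, with adjusted p = 2.91e-20 by camera and adjusted p = 0.0822 with an estimated correlation. Cholesterol synthesis rose in 13 of 14, with Sqle, squalene epoxidase, at 2.24 ± 0.08 (13 adjusted over the list alone). The median was 1.59, with adjusted p = 3.04e-10 by camera and adjusted p = 0.137 with an estimated correlation. Inflammatory genes rose in 10 of 15 and fell in 1, with Cxcl1 at 4.76 ± 0.08 (10 and 1 adjusted over the list alone). The median was 1.80, with adjusted p = 6.07e-06 by camera and adjusted p = 0.0882 with an estimated correlation. Beside them Cd14 rose by 2.14 ± 0.11 and Cd68 by 0.96 ± 0.16, the 2 of 13 macrophage, endothelial and red cell markers that passed (2 adjusted over the list alone). The median was 0.61, and 1.05 on the spike-in scale, with adjusted p = 0.0411 by camera and adjusted p = 0.316 with an estimated correlation. That list call ended without PGC-1α plus DFO replicate 2 (adjusted p = 0.362) and on the spike-in scale (adjusted p = 0.112). Glycolysis rose in 10 of 15 and fell in 3, with Aldoc at 3.01 ± 0.22 (10 and 3 adjusted over the list alone), a call that also ended on the spike-in scale (adjusted p = 0.21). The median was 0.56, with adjusted p = 0.00822 by camera and adjusted p = 0.325 with an estimated correlation.

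Muscle differentiation genes fell in 18 of 20 (18 adjusted over the list alone), fast sarcomere genes in 11 of 13 (11) and slow and cardiac sarcomere genes in 12 of 14 (12, and 1 rise). Medians were -3.01, -2.10 and -2.33, with adjusted p = 4.04e-16, 8.44e-10 and 1.25e-10, and adjusted p = 0.166, 0.141 and 0.118 with an estimated correlation. Among them were Tnni2 at -3.03 ± 0.10, Casq2 at -2.90 ± 0.09 and cardiac troponin I, Tnni3, at -5.39 ± 0.32. Fatty acid oxidation fell in 15 of 20 and rose in 1, with Cd36 at -4.53 ± 0.30 and the lipase Lpl at -2.24 ± 0.10 (17 and 1 adjusted over the list alone). The median was -0.81, with adjusted p = 1.79e-08 by camera and adjusted p = 0.0882 with an estimated correlation. Branched chain amino acid breakdown fell in 11 of 17, with Ivd at -2.54 ± 0.09 (12 adjusted over the list alone). The median was -0.86, with adjusted p = 7.83e-07 by camera and adjusted p = 0.196 with an estimated correlation. The ATF4 list fell in 14 of 22 and rose in 5, with Psat1, of serine synthesis, at -1.87 ± 0.08 (14 and 5 adjusted over the list alone). The median was -0.57, with adjusted p = 0.00542 by camera and adjusted p = 0.316 with an estimated correlation. On the spike-in scale the medians of these lists were -2.57 for muscle differentiation, -1.66 for fast and -1.89 for slow and cardiac sarcomere genes, -0.42 for branched chain amino acid breakdown and -0.13 for the ATF4 list.

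The 8 mitochondrial lists of this paragraph fell on the deposited scale and had medians above 0 on the spike-in scale, which raises each gene of PGC-1α plus DFO alike. Fatty acid oxidation, given above, kept its fall there (median -0.37, adjusted p = 3.27e-08). Complex I fell in 18 of 33 and rose in 1, complexes II and III fell in 7 of 14, complex IV in 3 of 13, ATP synthase in 10 of 17 and the TCA cycle in 10 of 17. Adjusted over the list alone, the falls were 20, 8, 2, 12 and 11. Medians were -0.39, -0.34, -0.19, -0.34 and -0.37 on the deposited scale and 0.05, 0.10, 0.25, 0.10 and 0.07 on the spike-in scale, where all 5 calls ended. On the deposited scale adjusted p = 1.41e-06, 0.000703, 0.0366, 2.49e-05 and 2.18e-05, and adjusted p = 0.349, 0.271, 0.323, 0.243 and 0.166 with an estimated correlation. The complex IV call also ended without PGC-1α replicate 1 (adjusted p = 0.0563), PGC-1α replicate 2 (adjusted p = 0.0552) or PGC-1α plus DFO replicate 2 (adjusted p = 0.0593). Iron-sulfur and haem enzymes fell in 12 of 20 and rose in 1 (13 and 1 adjusted over the list alone), with Fech, ferrochelatase, at -1.06 ± 0.09 (adjusted p = 0.0565 on the spike-in scale). The median was -0.39, and 0.04 on the spike-in scale, with adjusted p = 0.000155 by camera and adjusted p = 0.166 with an estimated correlation. The mitochondrial ribosome fell in 40 of 72 and rose in 1 (45 and 1 adjusted over the list alone), and mitochondrial gene expression fell in 6 of 27 (6 adjusted over the list alone), a call that ended without PGC-1α plus DFO replicate 2 (adjusted p = 0.111). The medians were -0.39 (0.05 on the spike-in scale) and -0.12 (0.32 on the spike-in scale), with adjusted p = 1.29e-11 and 0.0139 by camera and adjusted p = 0.263 and 0.533 with an estimated correlation. On the spike-in scale camera still passed the mitochondrial ribosome as lower relative to other genes (adjusted p = 0.000163).

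Ndufs1 fell by 0.69 ± 0.08 (adjusted p = 0.00322; adjusted p = 0.291 on the spike-in scale), while Cs had -0.20 ± 0.08 (adjusted p = 0.128) and Esrra 0.16 ± 0.10 (adjusted p = 0.317). Slc40a1 fell by 2.52 ± 0.11 (adjusted p = 0.000189), and Tfrc had 0.01 ± 0.09 (adjusted p = 0.938). The leading rises besides Car9 were Sprr2h (7.54 ± 0.38), Pgf (5.70 ± 0.24), Ier3 (4.83 ± 0.10), Mgarp (4.81 ± 0.36) and Ccnf, cyclin F (4.81 ± 0.16). The leading falls besides Myog and Tnni3 were Ldb3 (-6.23 ± 0.41), Ogn (-5.41 ± 0.15), Pdlim3 (-5.36 ± 0.08) and C1qtnf3 (-5.33 ± 0.25). Limma passed 4662 genes, 2079 higher and 2583 lower, with 6780 at an unadjusted p under 0.05. The count was 2637 without PGC-1α replicate 1, 3084 without PGC-1α replicate 2 and 1942 in a fit of only these 4 arrays, and the share that was higher was 44.6% on the deposited scale against 80.9% on the spike-in scale.

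The interaction asked where the effect of the construct differed between cells with and without DFO. Cxcl1 stood apart, at 240 ± 2.62, 283 ± 11 and 304 ± 9.45 intensity units in GFP, PGC-1α and GFP plus DFO and 7654 ± 146 in PGC-1α plus DFO (SD, n = 2), an interaction of 4.42 ± 0.11 on the log2 scale (SE; limma adjusted p = 0.00186). Inflammatory genes as a list were more raised by the construct under DFO (6 of 15 passed upward, 10 adjusted over the list alone). The median was 1.53, with adjusted p = 2.71e-09 by camera and adjusted p = 0.0822 with an estimated correlation. Muscle differentiation genes were more lowered (2 of 20 passed downward, and 14, with 1 upward, adjusted over the list alone). The median was -0.79, with adjusted p = 1.67e-09 by camera and adjusted p = 0.253 with an estimated correlation. Complex I and the TCA cycle had positive medians of 0.36 and 0.40 (0.80 and 0.84 on the spike-in scale) with 0 members passing by limma over all genes (18, with 1 downward, and 9 adjusted over the list alone; adjusted p = 2.3e-11 and 3.01e-05, adjusted p = 0.251 and 0.166 with an estimated correlation).

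The other positive lists were complexes II and III, with 0 members passing by limma over all genes (1 adjusted over the list alone), iron-sulfur and haem enzymes, also 0 (8 adjusted over the list alone), and complex IV, 1 (3, with 1 downward, adjusted over the list alone). The medians were 0.19 and 0.24 and 0.09 (0.63, 0.68 and 0.53 on the spike-in scale), with adjusted p = 0.00134, 3.01e-05 and 0.0459 by camera and adjusted p = 0.287, 0.141 and 0.34 with an estimated correlation. Among single mitochondrial genes Cs had 0.54 ± 0.11 (adjusted p = 0.107) and Ndufs1 0.54 ± 0.11 (adjusted p = 0.11). Slow and cardiac sarcomere genes had a median of -0.44 (1 passed each way, and 7 downward and 1 upward adjusted over the list alone; adjusted p = 0.00607, adjusted p = 0.311 with an estimated correlation). In 5 more lists the median was negative on the deposited scale and positive on the spike-in scale: hypoxia-inducible factor targets (-0.21 and 0.23), glycolysis (-0.22 and 0.22), fast sarcomere genes (-0.40 and 0.04), undifferentiated-cell markers (-0.36 and 0.08) and collagens (-0.27 and 0.17). Their adjusted p were 0.0168, 0.00239, 0.000503, 0.0459 and 0.000311, and adjusted p = 0.293, 0.293, 0.278, 0.323 and 0.397 with an estimated correlation, with 8, 4, 5, 3 and 4 members lower and 2, 0, 0, 1 and 0 higher adjusted over the list alone. Over all genes limma passed 0, 0, 0, 1 and 2 of them downward and 1 hypoxia-inducible factor target upward.

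Other genes with positive interactions were Slc7a2, a cationic amino acid transporter (2.58 ± 0.24), Adamts4 (2.12 ± 0.18), Bcat1 (2.08 ± 0.12), Enpep (1.74 ± 0.15) and Myl2 (1.61 ± 0.15), with adjusted p from 0.0235 to 0.0373. Negative ones were Rgcc (-3.82 ± 0.18), Spsb4 (-3.05 ± 0.31), Pdlim3 (-2.77 ± 0.12), Tmem182 (-2.64 ± 0.23), Ogn (-2.54 ± 0.21) and Tgfb3 (-2.16 ± 0.13), with adjusted p from 0.00937 to 0.0443. Rgcc rose with the construct from 104 ± 1.44 to 733 ± 30.7 without DFO and fell from 708 ± 59.1 to 355 ± 46.9 with it. Myog had -1.22 ± 0.18 (adjusted p = 0.0676) and Slc40a1 -0.66 ± 0.15 (adjusted p = 0.132). Limma passed 101 genes, 42 upward and 59 downward, with 3165 at an unadjusted p under 0.05. The count rested on single arrays: it was 2 and 14 without GFP replicate 1 and 2, 5 and 18 without PGC-1α replicate 1 and 2, 77 and 1 without PGC-1α plus DFO replicate 1 and 2, and 0 and 2 without GFP plus DFO replicate 1 and 2, the 0 with 2089 at an unadjusted p under 0.05, and Cxcl1 had adjusted p = 0.0582 without GFP plus DFO replicate 1. Rgcc ended without GFP replicate 1 (adjusted p = 0.0674), PGC-1α replicate 1 (0.0566), PGC-1α plus DFO replicate 2 (0.0664) or GFP plus DFO replicate 1 (0.0804) or 2 (0.0678), and the other 10 genes ended without each of these 5 arrays and, but for Pdlim3, of GFP replicate 2 and PGC-1α replicate 2 too, with adjusted p up to 0.232. Slc7a2 (0.0522), Adamts4 (0.0552), Enpep (0.0552) and Ogn (0.0552) also ended without PGC-1α plus DFO replicate 1. The count was 3 on the spike-in scale, which moved the median interaction of all genes from -0.01 to 0.43, and each list by as much, and ended the same 10 genes (adjusted p from 0.0711 to 0.137), and 1467 with eBayes' trend and robust options. Of the list calls, complex IV ended without each array but GFP replicate 1 (adjusted p from 0.0544 to 0.135 in the 7 cases), the hypoxia-inducible factor targets without PGC-1α plus DFO replicate 1 (adjusted p = 0.0754), and the undifferentiated-cell markers without GFP replicate 1 (0.19), PGC-1α replicate 2 (0.162) or GFP plus DFO replicate 1 (0.062).

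The last comparison set both factors together against neither. Cs and Sdhb stayed higher than in GFP cells, at 6975 ± 226 against 3255 ± 6.79 intensity units (SD, n = 2; log2 change 1.10 ± 0.08, limma adjusted p = 0.00045) and 5435 ± 125 against 2857 ± 184 (0.93 ± 0.09, adjusted p = 0.00129), while Ndufs1 had 0.19 ± 0.08 (adjusted p = 0.129). Esrra rose by 2.36 ± 0.10 (adjusted p = 0.000113), Pdk4 by 2.87 ± 0.10 (adjusted p = 7.48e-05), Tfrc by 0.94 ± 0.09 (adjusted p = 0.00132) and Vegfa by 1.49 ± 0.09 (adjusted p = 0.000302). Myog fell by 6.30 ± 0.13 (adjusted p = 3.72e-05) and Slc40a1 fell by 2.98 ± 0.11 (adjusted p = 8.28e-05). Limma passed 5786 genes, 2451 higher and 3335 lower (42.4% higher, against 86% on the spike-in scale, which moved the median of all genes from -0.01 to 0.61 and each list by as much), with 7520 at an unadjusted p under 0.05, and 3046 in a fit of only these 4 arrays.

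Complex I rose in 16 of 33 and fell in 2, complexes II and III rose in 11 of 14, the TCA cycle rose in 10 of 17 and fell in 2, iron-sulfur cluster assembly rose in 10 of 18 and fell in 2, and iron-sulfur and haem enzymes rose in 10 of 20 and fell in 1. Adjusted over the list alone, the rises were 18, 12, 11, 12 and 12. Medians were 0.31, 0.59, 0.54, 0.64 and 0.46, with adjusted p = 0.000209, 4.94e-06, 0.000214, 0.000177 and 2.75e-05, and adjusted p = 0.462, 0.183, 0.192, 0.244 and 0.141 with an estimated correlation. Hypoxia-inducible factor targets rose in 23 of 25, cholesterol synthesis in 13 of 14 with 1 fall and inflammatory genes in 10 of 15 with 1 fall (23, 13 and 10 adjusted over the list alone; medians 1.95, 1.30 and 2.37; adjusted p = 3.8e-18, 1.76e-08 and 3e-06, adjusted p = 0.0822, 0.141 and 0.0882 with an estimated correlation). Muscle differentiation genes fell in 18 of 20, fast sarcomere genes in 10 of 13 and slow and cardiac sarcomere genes in 12 of 14 with 1 rise (19, 11 and 12 adjusted over the list alone; medians -3.47, -2.55 and -2.70; adjusted p = 3.29e-14, 1.56e-08 and 4.92e-08, adjusted p = 0.183, 0.149 and 0.141 with an estimated correlation). The ATF4 list fell in 14 of 22 and rose in 5, and antioxidant enzymes rose in 6 of 16 and fell in 1 (14 falls and 6 rises adjusted over the list alone; medians -0.74 and 0.28; adjusted p = 0.00622 and 0.0102, adjusted p = 0.323 and 0.378 with an estimated correlation). On the spike-in scale the medians of the muscle differentiation, fast sarcomere, slow and cardiac sarcomere, ATF4 and antioxidant lists were -2.85, -1.94, -2.09, -0.13 and 0.89.

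Calls near the threshold were mitochondrial gene expression (9 of 27 rose and 1 fell) and the mitochondrial ribosome (26 of 72 rose and 13 fell), the second ending without GFP replicate 2 (adjusted p = 0.108), either PGC-1α array (adjusted p = 0.0543) or PGC-1α plus DFO replicate 1 (adjusted p = 0.11). The medians were 0.17 and 0.17 (on the spike-in scale 0.79 and 0.79, adjusted p = 0.00139 and 0.00111), with adjusted p = 0.0118 and 0.0395 by camera and adjusted p = 0.526 and 0.684 with an estimated correlation. Adjusted over the list alone, 9 rose and 1 fell in the first and 27 rose and 16 fell in the second. Glycolysis rose in 11 of 15 and fell in 3, complex IV rose in 7 of 13 and fell in 2 and angiogenic factors rose in 6 of 11 and fell in 1, with the same counts adjusted over the list alone (medians 1.09, 0.31 and 0.92; adjusted p = 0.000965, 0.0188 and 0.019, adjusted p = 0.271, 0.293 and 0.213 with an estimated correlation), and the 3 calls ended on the spike-in scale (adjusted p = 0.136, 0.19 and 0.151). So did those of the partners and targets of PGC-1α (10 rose and 5 fell of 24, 11 and 5 adjusted over the list alone) and of the macrophage, endothelial and red cell markers (2 of 13 rose, 2 adjusted over the list alone), with adjusted p = 0.251 and 0.145. The medians were 0.23 and 0.40, with adjusted p = 0.0336 and 0.0355 by camera and adjusted p = 0.202 and 0.311 with an estimated correlation. Without GFP replicate 2 these 2 had adjusted p = 0.0711 and 0.0742, and without PGC-1α plus DFO replicate 2 the second had 0.245. Branched chain amino acid breakdown fell in 8 of 17 (9 adjusted over the list alone), a call that ended without GFP replicate 2 (0.0902), either PGC-1α array (0.0575) or PGC-1α plus DFO replicate 2 (0.128). The median was -0.33, and 0.29 on the spike-in scale, with adjusted p = 0.0492 by camera and adjusted p = 0.51 with an estimated correlation.

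Of the lists that passed in none of the 6 contrasts, haem synthesis and breakdown had adjusted p from 0.0951 to 0.927, and iron uptake, storage and export from 0.147 to 0.985. Cell cycle genes had adjusted p from 0.237 to 0.997, interferon and antiviral genes from 0.643 to 0.99, adipocyte markers from 0.102 to 0.856 and osteoblast markers from 0.864 to 0.963. Of the 17 interferon genes 1 fell and 0 rose with the construct without DFO by limma (1 and 0 adjusted over the list alone; median -0.12).

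The effects of the construct without and with DFO correlated across 18193 genes with r = 0.3, and with r = 0.715 among genes above the median level, where genes are not independent replicates. These 2 contrasts shared 621 genes that rose in both and 538 that fell in both, against 62.5 and 104 for independent lists, and 8 and 14 went opposite ways. The effects of DFO with GFP and with PGC-1α correlated with r = 0.558 (0.868 above the median level), with 1385 genes higher and 1621 lower in both, against 245 and 322. The effects of the construct and of DFO share the GFP arrays, and they correlated with r = 0.315 across all genes, where simulated groups with no effect gave 0.501 over 100 simulations, with a covariance of 0.169 against 0.0936. Of the genes called in both, 298 rose with the construct and fell with DFO, 133 fell and rose, 214 rose in both and 375 fell in both, against 112, 102, 106 and 108 for independent lists. A split of the controls, chosen after seeing the data, used 1 GFP array for the construct and the other for DFO, so each effect rested on a single control array. In the 2 orders it gave r = 0.0598 and 0.0424 (0.0762 and 0.0711 above the median level), with covariances of 0.0404 and 0.0283, across genes that are not independent replicates. Much of the correlation with r = 0.315 therefore came from the shared GFP arrays.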

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

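The tests of the 3 patterns weighed here were all written after the pattern had been seen, and the results listed before them came from the planned interaction contrast or from control probe sets that no comparison of genes used.

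The effect of the construct differed between cells with and without DFO for 24 named genes, by the interaction test of limma (n = 2 arrays per group, interactions on the log2 scale ± SE). Positive interactions were Saa3 at 6.95 ± 0.81, Cxcl5 at 4.97 ± 0.50, Cxcl1 at 4.42 ± 0.11, Slc7a2 at 2.58 ± 0.24, Adamts4 at 2.12 ± 0.18, Bcat1 at 2.08 ± 0.12 and Enpep at 1.74 ± 0.15. Saa3 read 9.21 ± 3.22 intensity units with GFP plus DFO and 10.8 ± 7.70 with PGC-1α (SD), below the 25th percentile of every array (18.6 to 21.8), so the size of its interaction and its place in this order rest on readings near the floor. Smaller ones were Myl2 at 1.61 ± 0.15, Nefm at 1.56 ± 0.18, Setd5 at 1.46 ± 0.16, Cox6a2 at 1.26 ± 0.12 and Hspe1 at 1.12 ± 0.12. Negative interactions were Rgcc at -3.82 ± 0.18, Spsb4 at -3.05 ± 0.31, Pdlim3 at -2.77 ± 0.12, Tmem182 at -2.64 ± 0.23, Ogn at -2.54 ± 0.21, Tgfb3 at -2.16 ± 0.13 and Chrng at -1.84 ± 0.13. Postn had -1.68 ± 0.13, Ckmt2 -1.46 ± 0.17, Srxn1 -1.33 ± 0.16, Ccn2 -1.24 ± 0.12 and Casq2 -1.09 ± 0.12. Adjusted p ran from 0.00186 for Cxcl1 to 0.05 for Saa3, Ckmt2 and Srxn1, and without GFP plus DFO replicate 1 limma passed 0 genes, with 2089 at an unadjusted p under 0.05.

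By camera 13 lists differed in the same contrast. Medians above 0 were 1.53 for inflammatory genes, 0.397 for the TCA cycle, 0.36 for complex I, 0.237 for iron-sulfur and haem enzymes, 0.187 for complexes II and III and 0.0905 for complex IV. On the spike-in scale these 6 were higher, at 1.97, 0.837, 0.8, 0.677, 0.627 and 0.53. The median of -0.793 for muscle differentiation genes was -0.353 on the spike-in scale, and that of -0.442 for slow and cardiac sarcomere genes was -0.00231 there, about 0. Those of fast sarcomere genes (-0.399), undifferentiated-cell markers (-0.358), collagens (-0.268), glycolysis (-0.221) and hypoxia-inducible factor targets (-0.21) turned positive there. The camera calls of the last 3 of these ended there (adjusted p = 0.0643, 0.0947 and 0.221). With an estimated correlation camera passed 0 of the 204 list tests, with 53 at an unadjusted p under 0.05 and 152 passed by fry.

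Control probe sets for the transferrin receptor, which no gene comparison used, were higher with PGC-1α than with GFP by a log2 change of 1.89 ± 0.38 (adjusted p = 0.0354). The probe set used for Tfrc rose by 0.93 ± 0.09.

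Inflammatory genes rose with the construct under DFO more than without it. With values floored at the 25th percentile of each array the median interaction was 1.27, which argues against signals near the floor as the whole cause. Of 7 macrophage markers 0 passed by limma between the 2 DFO groups, with a median log2 change of 0.0191 and Csf1r at 1495 and 1682, which argues against RNA from macrophages. Leaving out either array of PGC-1α plus DFO left a median of 1.42 or more, so the pattern did not rest on 1 of them. A response of the cells to the construct in the presence of DFO may explain it, as may a difference in the amount of virus or in the state of the cultures, and these were not tested.

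Muscle differentiation genes fell with DFO in GFP cells. A larger share of undifferentiated cells would raise their markers together, but 6 of 16 fell and 4 rose, although some of these markers may also be expressed in myotubes. An error of array scaling would move every gene alike, but the list's median lay at -1.93 relative to that of all genes (interquartile half-width 0.678) while hypoxia-inducible factor targets rose, and the poly-A spike-ins differed by 0.00 ± 0.12, which argues against array scaling. A lower expression of muscle genes within the cells, or a loss of myotubes to a state these markers do not cover, could each give the pattern, and the 2 were not tested.

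Tfrc had a log2 change of 0.16 ± 0.09 with DFO in GFP cells (adjusted p = 0.287). The same probe set rose by 0.93 with the construct, which argues against saturation, and the other Tfrc probe sets had a mean change of -0.367 (SE 0.284) with DFO. The median of 2.28 among hypoxia-inducible factor targets argues against DFO having had no action on the cells. Levels that had returned from an earlier rise before RNA was taken could be an explanation, and no earlier time point was analysed here. How long the cells were exposed to DFO is not stated here.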

How the results depend on the processing

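Scaling to the poly-A spike-ins and splitting the GFP arrays were chosen after seeing the data, and each other alternative was chosen before the data were examined. The count of genes past the threshold for the interaction, 101 on the values as deposited, was 216 with quantile normalization, 4 with the mean of a gene's probe sets, 58 without probe sets ending in _x_at or _s_at, 11 with every probe set on its own, 1316 among genes above the median level, 447 with the floor, 1467 with eBayes' trend and robust options, 3 with the replicate block and 3 on the spike-in scale. For the construct without DFO, 1770 became 940 with the mean of probe sets, 3524 among genes above the median level, 3746 with trend and robust options, 543 at 2-fold, 1060 with the replicate block and 508 on the spike-in scale. A limma fit of only the groups compared passed 0 there, with 4531 at an unadjusted p under 0.05. For the construct with DFO, 3446 became 2213 with the mean of probe sets, 861 with only the groups compared and 1060 at 2-fold. For DFO with PGC-1α, 4662 became 7068 with every probe set, 1942 with only the groups compared and 1866 at 2-fold, and for both factors together 5786 became 9289, 3046 and 2501. For DFO with GFP, 4409 became 1672 at 2-fold and 2230 on the spike-in scale. The 2-fold counts follow from the added limit on the change, and the counts with every probe set are of 45037 probe sets and not of genes. For DFO with GFP the spike-in scale left the changes the same size (median of all genes -0.0174 and -0.0177). The lower count there came from a larger spread between the arrays of a group and not from smaller changes. The poly-A spike-ins read 438 and 372 on the 2 arrays of GFP plus DFO. For the other counts the cause was not tested. Deviations of arrays with the same number correlated across genes, which are not independent replicates, with r from -0.0247 to 0.0322, and from -0.11 to 0.221 among genes above the median level. With 2 arrays per group these values do not settle whether the numbers pair the samples.

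Leaving out 1 array, which assumes that the lone array of a group varies like the others, gave 304 to 2094 genes for the construct without DFO, 2069 to 4695 for DFO with GFP, 873 to 3431 for the construct with DFO, 2637 to 4130 for DFO with PGC-1α, 0 to 77 for the interaction (limma, 2089 at an unadjusted p under 0.05 at the 0, without GFP plus DFO replicate 1) and 4114 to 5281 for both together. The 109 list calls became 103 to 110. With an estimated correlation camera passed 0 (53 at an unadjusted p under 0.05), and fry passed 152. The correlation of the construct's effects without and with DFO, 0.3, was 0.261 with the mean of probe sets, 0.715 among genes above the median level, 0.532 with the floor and 0.244 to 0.281 with an array left out. That of the DFO effects, 0.558, was 0.868, 0.763 and 0.494 to 0.54 for the last 3 of these. That of the construct and DFO, 0.315, was 0.104 among genes above the median level and 0.262 to 0.499 with an array left out. With the GFP arrays split it was 0.0598 and 0.0424. Genes are not independent replicates in these values.

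Some named genes changed direction. With the mean of probe sets Atp5g1 had -0.20 with the construct, Ppargc1a -0.84 with DFO in GFP cells, -0.96 in PGC-1α cells and -0.11 with both factors, Becn1 0.11 and Fdps 0.29 with the construct under DFO, and Rsad1 0.0897 with DFO in PGC-1α cells. Without _x_at and _s_at probe sets Ager had 0.13, Reep1 0.78 and Atp5c1 -0.45 with the construct and Angptl4 -0.56 with DFO in GFP cells. On the spike-in scale Fundc1 had 0.20, Fdft1 0.0378, Fdps 0.0786, Cyp51 0.0941 and Cblb 0.0945 with the construct under DFO, Uqcrfs1 0.0362, Sdha 0.0405 and Cox7a1 0.0886 with DFO in PGC-1α cells and Fth1 0.24 with both factors, since that scale raises each gene of PGC-1α plus DFO alike. The lysosome list, with a median of 0.385 there for the construct under DFO, was the one called list whose direction by camera turned. The cause was not tested for the others. Of 204 list results 204 kept their side of the threshold, and where called the direction that camera gives relative to other genes, with trend and robust options, 200 with median centring, 200 with the replicate block, 195 with quantile normalization and 176 on the spike-in scale. Camera's direction is not the sign of the median: on the spike-in scale the median turned sign in 8 of 19 called lists for DFO with PGC-1α, 5 of 20 for the construct with DFO, 5 of 13 for the interaction and 1 of 21 for both together, some of which stayed called. Signal over background limits dim genes, whose median SD of log2 intensity was 0.212 to 0.306 against 0.0556 to 0.112 for bright ones.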

Other observations

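Genes named in this part were chosen after their values were seen, and the 4 added families were chosen after the results for other lists were known, with their tests written before the families' own values were computed.

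The list of haem synthesis and breakdown did not pass camera with the construct or with DFO in GFP cells (adjusted p = 0.0951 and 0.37), nor did that of iron uptake, storage and export (adjusted p = 0.66 and 0.985). Of single genes, Alas1, the first enzyme of haem synthesis, went from 576 to 2085 intensity units with the construct (log2 change 1.86 ± 0.09, SE, n = 2; limma adjusted p = 0.00186) and fell by 0.65 with DFO in GFP cells (adjusted p = 0.00714). Hmox1, which breaks haem down, went from 717 to 2312 with DFO (1.69, adjusted p = 0.000542). Cp, ceruloplasmin, rose by 1.29 with DFO (adjusted p = 0.00119). Slc11a2, an iron importer, fell by 0.52 with DFO (adjusted p = 0.00729) and rose by 1.18 with the construct under DFO (adjusted p = 0.00132).

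Cell cycle genes went both ways with the construct without DFO. Rrm2, a subunit of the iron enzyme ribonucleotide reductase, rose by 2.34 (adjusted p = 0.00168), and Mcm6, of the replicative helicase, fell by 1.59 (adjusted p = 0.00664). Cdh15, M-cadherin, fell by 2.18 with DFO in GFP cells (adjusted p = 0.000277), and Trim63 fell by 1.41 with the construct (adjusted p = 0.0159).

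Cytosolic heat shock genes besides Hspa1a and Hspa1b fell with the construct in 7 of 14, with a median of -0.4 (adjusted p = 0.000156, adjusted p = 0.301 with an estimated correlation). Coenzyme Q synthesis rose with the construct in 7 of 11, with a median of 0.725 (adjusted p = 7.95e-08, adjusted p = 0.297 with an estimated correlation), and fell with DFO in 9 of 11 (median -0.652, adjusted p = 1.47e-05, adjusted p = 0.297 with an estimated correlation). The iron-dependent JmjC demethylases and TET enzymes rose with DFO in 5 of 16 and fell in 2, with a median of 0.305 (adjusted p = 0.0345, adjusted p = 0.301 with an estimated correlation). Peroxisome genes rose with the construct in 2 of 18, Phyh by 2.63 and Pex2 by 0.71, and fell in 0. The median was 0.134 (adjusted p = 0.0345, adjusted p = 0.358 with an estimated correlation). At the preset correlation camera passed each family in the direction that had been written down, and with an estimated correlation it passed none of the 16 tests, with 1 of them, coenzyme Q with the construct, at an unadjusted p under 0.05.

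In the other contrasts of these families, heat shock genes fell with DFO in GFP cells in 10 of 14 and rose in 2 (median -0.549, adjusted p = 0.000913, adjusted p = 0.301 with an estimated correlation). They fell with DFO in PGC-1α cells in 6 and rose in 1 (median -0.282, adjusted p = 0.0286, adjusted p = 0.358 with an estimated correlation), and did not pass with the construct under DFO (median -0.177, adjusted p = 0.0757). Coenzyme Q synthesis rose with the construct under DFO in 8 of 11 and fell in 1 (median 0.691, adjusted p = 3.65e-05, adjusted p = 0.297 with an estimated correlation). It fell with DFO in PGC-1α cells in 8 (median -0.572, adjusted p = 1.47e-05, adjusted p = 0.297 with an estimated correlation). The demethylases and TET enzymes did not pass with the construct without or with DFO or with DFO in PGC-1α cells (medians -0.192, -0.11 and 0.144, adjusted p = 0.571, 0.49 and 0.0881). Peroxisome genes fell with DFO in GFP cells in 7 of 18 (median -0.334, adjusted p = 0.00816, adjusted p = 0.301 with an estimated correlation). With the construct under DFO 6 rose and 2 fell (median 0.165, adjusted p = 0.0128, adjusted p = 0.301 with an estimated correlation), and with DFO in PGC-1α cells the list did not pass (median -0.21, adjusted p = 0.0579). These families were not run on the spike-in scale, so the contrasts with PGC-1α plus DFO are relative to the deposited scale.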
